A study of Danio rerio with 8 samples.

How the data were processed

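Messenger RNA was sequenced from chondrocytes of zebrafish (Danio rerio) larvae. Per the labels' protocols, larvae were raised at 28.5 degrees Celsius in medium with 0.003% PTU, a compound that blocks pigment formation, and cells positive for both a sox10:EGFP and a col2a1a:mCherry reporter were sorted from whole larvae at 3 days after fertilisation. Libraries were made with a directional RNA-seq kit, per the labels' protocols. The 8 libraries fall into 2 groups of 4, WT and kat6a-deficient, and the series design calls them biological replicates, so p-values measure the spread between such samples. The nature of the kat6a lesion, and whether the WT larvae were siblings, are not given in the sources used here. The library name in the label of WT replicate 4 repeats the number 3, while its title gives 4 and its library index is its own, so the title was followed.

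The authors deposited 1 table of FPKM values, which are fragments scaled by transcript length and by the mapped fragments of the library, for 32057 genes, 1 row per Ensembl gene ID. HISAT2 and StringTie and the genome build GRCz10 are named in the submitters' processing notes without versions or settings. The table also holds the authors' fold (a ratio of WT over kat6a) with a p-value and a q-value per gene, per the file headers; 12613 genes carry no p. Some gene IDs may postdate GRCz10, and the annotation behind them is not given in the sources used here. Columns of per-library values that could not be tied to a sample numbered 0. Symbols came from a table of gene IDs and names, in which 28988 of the 32057 IDs were found. Coordinates were not used, because the reference at hand is of another build (GRCz12tu); it served only to find which genes share a chromosome or neighbour each other.

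FPKM keeps no read counts, so the depth of each library is unknown and no counting interval or detection floor was computed. The low values showed no common step. Deposited FPKM summed to between 311061 and 339307 per library, and 11010 to 16108 genes stood above 0. All 13 genes of the mitochondrial genome were listed at 0 in every library, 17 of 54 proteasome and RNA polymerase II subunit genes were listed at 0 in at least 1 library, and so were 21 of 2837 genes with a median FPKM of at least 10. An exact 0 was therefore read only as a listed value, and genes with such values are given library by library, without a mean.

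Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) as deposited, for the 11763 genes with a mean FPKM of at least 0.5 over the 8 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and also counted at a fold of at least 2 (log2 of at least 1). Fold changes are kat6a over WT on the log2(FPKM + 1) scale, which understates the change of low genes. All tests were two-sided. The 38 gene lists were fixed before the data were examined, as were the groups, the tests and most of the alternatives. They cover insulin-like growth factor (IGF) ligands and receptors, IGF binding and release, lymphatic and vascular ligands, cartilage matrix, chondrogenic transcription factors, hypertrophy and bone, hox genes, pharyngeal arch patterning, MYST complexes, cell cycle, p53 and CDK inhibitors, hedgehog, BMP, WNT, FGF, retinoic acid and TGF-beta or YAP targets, the secretory pathway, glycosaminoglycan synthesis, glycolysis and hypoxia, cholesterol synthesis, interferon response, immediate early and stress genes, ribosomal proteins, the mitochondrial genome, and markers of pigment cells, Schwann cells and glia, neurons, muscle, blood, leukocytes, endothelium, epidermis, inner ear, notochord and fin fold, tendon and perichondrium, liver with pancreas and gut, and lens with retina. The 35 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run beside it with its directional p. Members called were counted with p adjusted over all genes and adjusted over the list alone.

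Genes are named by a rule fixed before the data were examined: up to 12 rises and 12 falls among called genes whose groups do not overlap and whose symbol is a gene name; kat6a and the measured MYST complex members; from each list up to 4 called members, or where none was called up to 2 with the smallest p, given as values; and igf1, igf2a, igf2b, the igf1r and igfbp genes and vegfc. The text may leave out members of the first kind and of the lists for length. A gene that the rule names is not reported here for another reason, and it stayed in every test. Other genes are named with a remark that they were chosen after their values were seen. Single comparisons of 4 against 4 used an exact permutation test, whose smallest p is 0.0286.

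Libraries of the 2 groups share replicate numbers. The deviations from the group mean correlated across genes with r = 0.589, 0.347, 0.127 and 0.151 for the pairs numbered 1 to 4. Each was above 0.1, and the numbers were taken to pair the libraries. Libraries of different number reached 0.158, for WT replicate 2 with kat6a replicate 3, and 0.157, for WT replicate 3 with kat6a replicate 2. The threshold therefore does not set the pairs numbered 3 and 4 apart from mismatched ones. The pairing comes from the data, since the labels name no shared day, and 6 of the 8 libraries matched best with their own number. The fit without the pair term was the main one, as fixed beforehand, and the fit with replicate number as a block is given where it changed a call. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 1, median-ratio, quantile and upper-quartile scaling, the replicate block, robust limma, array weights and each library left out in turn. Leaving out the pair numbered 1, and the block combined with median-ratio scaling or with array weights, were added after the data were seen.

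The procedure was tested on simulated data with the means and spread of the 11763 genes, in 5 runs with 200 genes changed in each. It recovered 14.6% of genes changed 2-fold and 66.2% of those changed 4-fold on the log2(FPKM + 1) scale, with 3.35% of calls false. Values were drawn from a normal distribution, with no effect shared by replicate number and no values listed at 0. These rates may therefore not hold for the real libraries. Camera called 10 of 10 changed lists of 20 genes and 0 of 30 unchanged lists. Genes were drawn independently there, while the real muscle list, for example, had an estimated correlation of 0.69 between members. The simulation therefore cannot show how often camera falsely calls lists whose members move together. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.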

Results

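RNA from sorted chondrocytes, the cells that build cartilage, was profiled in 4 WT and 4 kat6a-deficient libraries of zebrafish larvae at 3 days after fertilisation. The sorted cells carried both a sox10 reporter, which marks neural crest and its derivatives, and a col2a1a reporter, which marks cartilage. The kat6a gene encodes a histone acetyltransferase of the MYST family. The comparison asks how deficiency of kat6a changes gene expression in these cells, in a study whose title concerns IGF signalling and lymphatic vessels. Values are FPKM as deposited. The number of genes above 0 was 15769, 16108, 13483 and 14302 in WT replicates 1 to 4 and 12541, 13429, 15351 and 11010 in kat6a replicates 1 to 4, and depth is unknown.

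Cartilage genes dominated every library. The collagen gene col2a1a stood at 16792 ± 5324 FPKM in WT and 16736 ± 4087 in kat6a (SD, n = 4 each), and matn1, a cartilage matrix protein gene, at 17228 ± 6428 and 18800 ± 5244. Much of that spread came from the libraries numbered 1. There col2a1a was 8994 FPKM in WT and 10783 in kat6a, against 17360 to 20538 in the other 6 libraries, while acana, the gene of the proteoglycan aggrecan, was 2389 and 2127 FPKM against 1240 to 1636. These genes were chosen to describe the sort after their values were seen. The first principal component held 41.2% of the variance and set both libraries numbered 1 apart from the rest. The 10 genes with the highest mean over the 8 libraries took 12.4% of summed FPKM in WT replicate 1 and 16.1% in kat6a replicate 1. Their share was 25.1% to 29.2% elsewhere. The 10 genes were not chosen library by library. The range of Pearson correlations between libraries was 0.848 to 0.955 within a group and 0.898 to 0.956 for libraries that share a number.

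**Figure D1:**
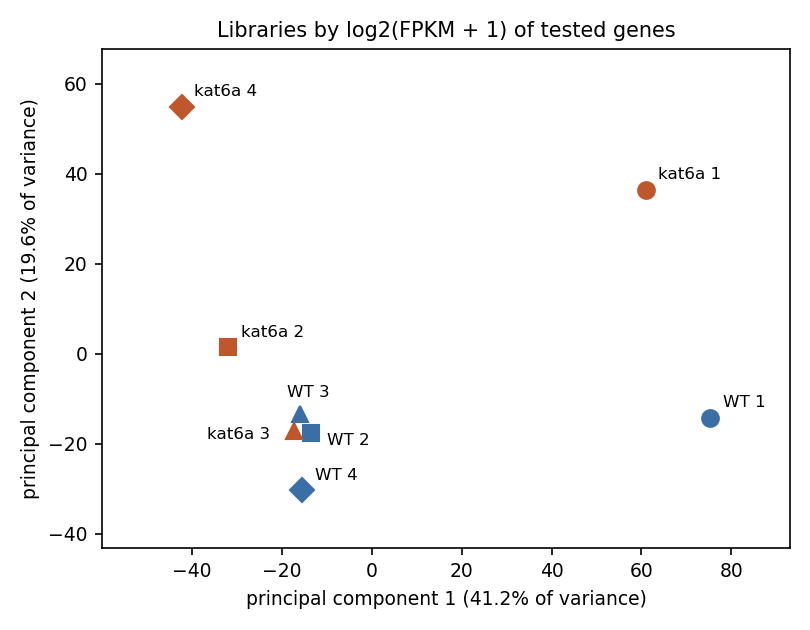
Principal components 1 and 2 of log2(FPKM + 1), in arbitrary units, with 1 point per library, WT in blue and kat6a in orange, and marker shape for the replicate number. WT 1 and kat6a 1 lie at 75.35 and 60.99 on component 1 and the other 6 libraries between -42.25 and -13.54.

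The targeted gene itself was measured first. Its FPKM was 32.0, 15.2, 16.3 and 18.9 in WT replicates 1 to 4 and 28.2, 11.98, 12.4 and 9.09 in kat6a replicates 1 to 4, lower in the kat6a library of 4 of 4 pairs. The kat6a mean was 74.9% of the WT mean. The log2 fold change was -0.46 ± 0.36 (SE), with limma adjusted p = 0.958 and an exact permutation p of 0.314, so the difference did not exceed the spread between libraries. With the replicate block the unadjusted limma p for this gene was 0.0315, and an exact sign-flip test over the 4 pairs gave 0.125, the smallest it can give. The limma adjusted p was 0.458 with the block and 0.322 or more in every fit. Without kat6a replicate 1 the log2 fold change was -0.78 with an unadjusted limma p of 0.0216, a move of over 1.5 times. Transcript level alone does not check the labels, because a lesion can leave the transcript in place.

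Of the 12 tested members of the MYST complexes, which pair these acetyltransferases with scaffold and reader subunits, none was called by limma and none reached an unadjusted p under 0.05. The paralog kat6b had a log2 fold change of -0.077 ± 0.57 (SE), kat7b of -0.096 ± 0.26 and kat8 of -0.16 ± 0.26; kat6b and kat7b turned sign under each scaling, and kat8 under quantile and upper-quartile scaling, as did brd1a, while brpf3b turned under upper-quartile scaling. Among scaffold and reader genes the values were -0.33 ± 0.26 for brpf1, 0.093 ± 0.27 for brpf3a, -0.25 ± 0.40 for brpf3b, -0.17 ± 0.28 for brd1a and -0.36 ± 0.38 for brd1b. The subunit genes ing4, ing5a and meaf6 had 0.35 ± 0.28, 0.41 ± 0.29 and -0.57 ± 0.35. The list as a whole had a camera adjusted p of 0.853.

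Lens genes were lower in the kat6a libraries. The 2 genes called by limma were mipb (ENSDARG00000013963), a lens aquaporin gene, and cryba4 (ENSDARG00000024548), a beta crystallin gene, and both fell. FPKM of mipb was 6.08, 9.67, 7.16 and 6.30 in WT and 0, 0, 0.146 and 0.621 in kat6a, a log2 fold change of -2.81 ± 0.28 (SE) with limma adjusted p = 0.0190. For cryba4 FPKM was 6.76, 24.1, 9.76 and 13.8 in WT and 0, 0.952, 0.200 and 0 in kat6a, a log2 fold change of -3.42 ± 0.40 with limma adjusted p = 0.0343. Each was lower in 4 of 4 pairs and at least 2-fold lower. Each was also listed at 0 in 2 kat6a libraries, and its fold change and p rest on taking those listed values as levels.

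Other crystallin genes, named here after their values were seen, had values of the same kind without passing the threshold over all genes. FPKM of crybb1 was 25.7, 88.5, 30.2 and 52.8 in WT and 0, 0.743, 1.61 and 7.64 in kat6a. For crygmx it was 18.4, 41.4, 29.7 and 30.2 in WT and 0, 0, 0 and 7.18 in kat6a, and for cryba1b 7.46, 21.7, 5.17 and 6.12 in WT and 0, 0, 0.131 and 1.15 in kat6a. The limma adjusted p was 0.0984 for each. FPKM summed over 56 crystallin genes was 195 ± 124 in WT and 12.4 ± 18.7 in kat6a (SD, n = 4), with no overlap. The exact permutation p was 0.0286, the smallest possible. This sum was chosen after values of its genes were seen, so that p is no independent evidence. The sum made up 0.0606% of all FPKM in WT and 0.00389% in kat6a. Much of the kat6a sum came from kat6a replicate 4, at 40.4 FPKM against 1.77 to 4.37 in the other 3; without it the kat6a mean was 3.05 FPKM, or 0.000932%. Crystallin copies are similar in sequence and may share reads, so the value of a single copy is uncertain. In the list of lens and retina markers 1 of 11 members fell with p adjusted over all genes and 6 fell adjusted over the list alone, namely cryba4, crybb1, crygn2, cryba1b, cryba2a and mipa. The median log2 fold change was -1.33, with a camera adjusted p of 9.79e-13, an adjusted p of 0.198 with an estimated correlation, and a fry adjusted p of 0.0459. The camera call held in all 20 alternatives, while the fry call held in 7 of them, among them the block combined with median-ratio scaling, at 0.0468. Neither camera nor fry used the robust setting, so robust limma could only repeat their main results. Fry did not use array weights either, so its results with array weights, with or without the block, repeated those without weights. Without the block the fry call ended under each scaling, up to an adjusted p of 0.269. It ended too with a pseudocount of 0.1, at 0.105, without a filter, at 0.0704, and without the pair numbered 1, at 0.167. It also ended without any one of 7 libraries, up to 0.189, the exception being kat6a replicate 4.

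**Figure D2:**
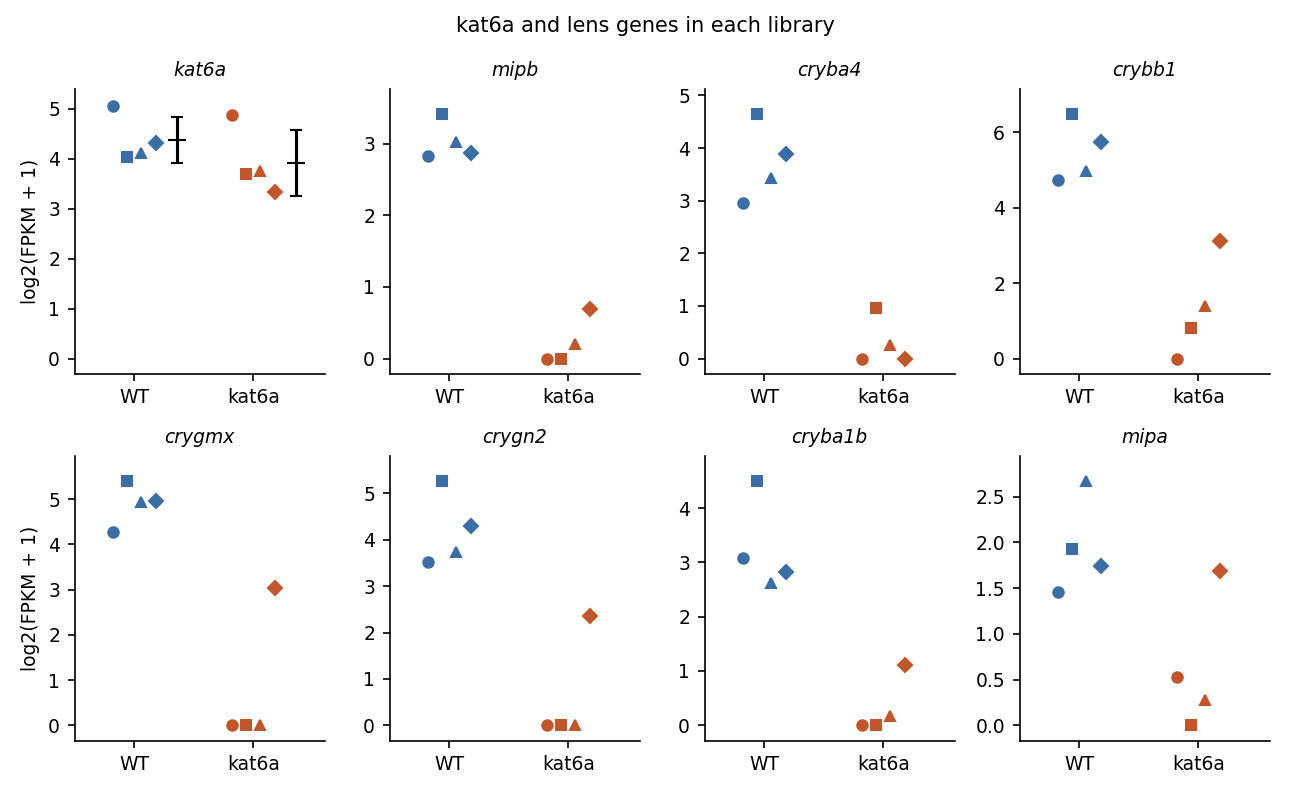
FPKM of kat6a and 7 lens genes on a log2(FPKM + 1) scale, with 1 point per library, WT in blue and kat6a in orange, and circle, square, triangle and diamond for replicates 1 to 4. The bar with caps beside kat6a is the mean and SD of log2(FPKM + 1) (n = 4) and is left out for genes listed at 0 in some library; the kat6a libraries lie between 0 and 0.621 FPKM for mipb, below WT at 6.08 to 9.67.

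No gene rose with p adjusted over all genes, and at an unadjusted p under 0.05 limma gave 76 higher and 461 lower genes. The lower side is tied to the scale, because the median log2 fold change of all tested genes was -0.16. After median-ratio scaling the median was -0.039 and the split 182 higher to 342 lower; after quantile normalisation 0.017 and 235 to 227; and after upper-quartile scaling 0.13 and 361 to 192. None of those scalings called a gene, nor did the fit without a filter, and a pseudocount of 0.1 called 1 gene, si:ch211-255g12.6, and neither mipb nor cryba4. The groups did not overlap for 368 genes, 66 higher and 302 lower, or 3.13% of tested genes, where chance gives 2.86%. By any amount 69.5% of tested genes were lower in kat6a. The share of tested genes lower in 4 of 4 pairs was not counted, so that pattern in a named gene is only a description. With the replicate block 1 gene was called, cryba4 at adjusted p = 0.0369, while mipb had 0.131; both were called when the pair numbered 1 was left out, among 4 genes that also held ubb and ela3l, all lower. The count was 0 without WT replicate 2, 3 or 4 or kat6a replicate 2 or 3 and 5 without kat6a replicate 4, namely mipb, crygmx, cryba1l1, crygn2 and crybb1; without kat6a replicate 1 it was 2, mipb and ubb; the call of cryba4 was also lost without kat6a replicate 1 or 4.

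Markers of other tissues moved in different directions. Muscle markers were higher in kat6a as a list, with a median log2 fold change of 0.42 over 19 members and a camera adjusted p of 2.5e-14, but an adjusted p of 0.464 with an estimated correlation. None rose over all genes in limma, 5 had an unadjusted p under 0.05, and mylpfb, a fast muscle myosin light chain gene, rose adjusted over the list alone, from 50.7 ± 5.76 FPKM in WT to 90.5 ± 17.2 in kat6a (SD, n = 4). The troponin gene tnnt3b stood at 21.6 ± 6.34 and 35.1 ± 1.53 FPKM. The number that rose adjusted over the list alone was 2 with the replicate block, mylpfb and tnnt3b, and the same 2 under median-ratio or quantile scaling and without WT replicate 1 or the pair numbered 1. It was 11 under upper-quartile scaling, 8 without WT replicate 4 and 7 with array weights, but 0 without WT replicate 2 or 3 or kat6a replicate 1, 3 or 4. Among the 3 leukocyte markers that passed the filter, of 19 on the list, laptm5 and mfap4 rose adjusted over the list alone. Their log2 fold changes were 0.79 ± 0.24 (SE) and 0.73 ± 0.26. Without a filter 3 of 10 members had a log2 fold change above 0, and the median was -0.055. In the main fit the list's camera adjusted p was 0.00381, and the adjusted p with an estimated correlation 0.209. That list call was lost without WT replicate 1, at 0.133, without a filter, at 0.211, and with array weights, at 0.0564. Neither marker passed over the list alone without a filter, WT replicate 3, kat6a replicate 3 or kat6a replicate 4, and laptm5 alone did without WT replicate 1, WT replicate 2, kat6a replicate 1 or the pair numbered 1 and with array weights.

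Liver, pancreas and gut markers were lower as a list. Their median log2 fold change was -0.82 over 16 members and the camera adjusted p 7.84e-05, with an adjusted p of 0.713 with an estimated correlation. None fell over all genes in limma, 8 had an unadjusted p under 0.05, and the same number fell adjusted over the list alone. That number was 3 with the replicate block or without WT replicate 2, namely apoa2, serpina1 and cpa5, 4 with a pseudocount of 0.1, adding fabp10a, and 2 without a filter, tfa and serpina1. It was 0 under median-ratio, quantile or upper-quartile scaling and without WT replicate 3, WT replicate 4, kat6a replicate 2 or kat6a replicate 4. The pancreatic carboxypeptidase gene cpa5 stood at 3.53, 10.5, 30.5 and 37.6 FPKM in WT and 2.56, 0, 5.52 and 0 in kat6a, and the apolipoprotein gene apoa2 at 6.22 ± 2.43 and 2.12 ± 1.13 FPKM (SD, n = 4). Epidermal markers had a median of -0.83 over 16 members and a camera adjusted p of 0.00868, with an adjusted p of 0.789 with an estimated correlation. The keratin gene krtt1c19e was 178 FPKM in WT replicate 4 and 0 to 17.7 in the other 7 libraries; it fell adjusted over the list alone with the replicate block, which gave 1 member, while without the block none fell in limma and 1 had an unadjusted p under 0.05. The epidermal call was lost without WT replicate 4, kat6a replicate 1 or kat6a replicate 2, with a largest adjusted p of 0.709, and without a filter, at 0.0698, while the muscle, liver and lens calls held with each library left out.

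Cartilage matrix genes differed little. Their median log2 fold change was 0.078 over 26 members, none of which was called by limma without the block, adjusted over all genes or over the list alone, and 1 of which, fmodb, had an unadjusted p under 0.05. In 2 blocked fits mia rose adjusted over the list alone, with a log2 fold change of 0.50 with median-ratio scaling and 0.38 with array weights. The list was higher relative to other genes by camera at adjusted p = 0.00276, with an adjusted p of 0.721 with an estimated correlation, and it was not called without WT replicate 1, kat6a replicate 2 or kat6a replicate 4. Without WT replicate 1 the mean was -0.093, with the largest adjusted p, 0.726; quantile normalisation and array weights also ended the call, at 0.668 and 0.143. The proteoglycan gene snorc was 585 ± 67.2 FPKM in WT and 717 ± 72.5 in kat6a (SD, n = 4), higher in 4 of 4 pairs, and fmodb was 0.501, 0.271, 1.53 and 2.25 FPKM in WT and 0, 0, 0.313 and 0 in kat6a. Of the chondrogenic transcription factors foxf1 had a log2 fold change of -0.52 ± 0.27 (SE) and foxf2a of -0.52 ± 0.28, each lower in 4 of 4 pairs; with the block and array weights foxf1 and trps1 fell adjusted over the list alone. In the hypertrophy and bone list pth1ra, a parathyroid hormone receptor gene, had -0.39 ± 0.22 and entpd5a 0.44 ± 0.35. The xylosyltransferase gene xylt1, of glycosaminoglycan synthesis, had -0.29 ± 0.16 and the sulfotransferase gene chst3a 0.37 ± 0.19. That list was called higher with the replicate block, at camera adjusted p = 0.0396, against 0.0619 without it; its adjusted p with an estimated correlation in the blocked fit was 0.701. It was called in 11 of 20 alternatives, among them those without WT replicate 2, 3 or 4 or kat6a replicate 1 or 3, down to 0.00609, and with an estimated correlation the adjusted p in those 11 was 0.525 to 0.802.

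Ribosomal protein genes were higher as a list, with a median log2 fold change of 0.085 over 71 members and a camera adjusted p of 7.46e-13. The adjusted p with an estimated correlation was 0.713, and quantile normalisation ended the camera call, at 0.791; without the block no member was called by limma over all genes or over the list alone, and 2 had an unadjusted p under 0.05, or 12 with the block. With the block and median-ratio scaling 9 rose adjusted over the list alone, rpl35 among them. Here rpl35 was 770 ± 62.6 FPKM in WT and 932 ± 23.2 in kat6a (SD, n = 4), while rpl29 was 18.9, 194, 25.7 and 275 in WT and 223 to 259 in kat6a. Targets of TGF-beta and YAP were higher by camera at adjusted p = 0.00909, with an adjusted p of 0.209 with an estimated correlation, and the call was lost without WT replicate 1, WT replicate 4 or kat6a replicate 4, up to 0.133, and with quantile normalisation, at 0.318, or array weights, at 0.0954. None of its members was called by limma and 1 had an unadjusted p under 0.05. The matricellular gene ctgfa had a log2 fold change of 0.71 ± 0.32 (SE) and cyr61l1 of 0.77 ± 0.57, each higher in 4 of 4 pairs. Without kat6a replicate 4 ctgfa stood at 0.44, without kat6a replicate 1 at 0.99, where it rose adjusted over the list alone, and under upper-quartile scaling at 1.11, while cyr61l1 stood at 0.16 without WT replicate 1 and 0.45 without the pair numbered 1. WNT targets were lower by camera at adjusted p = 0.0330, with an adjusted p of 0.634 with an estimated correlation; limma called none of the 6 members and 2 had an unadjusted p under 0.05. That call was lost with the replicate block, at 0.0937, and without WT replicate 1 or kat6a replicate 1, 3 or 4, up to 0.124; a filter at a mean FPKM of 1, quantile normalisation and array weights ended it too. Its members lef1 and znrf3 had -0.84 ± 0.32 and -0.87 ± 0.35.

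Immediate early and stress genes were lower as a list, with a median log2 fold change of -0.37 over 25 members and a camera adjusted p of 0.0422; the adjusted p with an estimated correlation was 0.825. Without the block 0 members fell adjusted over the list alone in limma, and 6 had an unadjusted p under 0.05. With the replicate block 10 members fell adjusted over the list alone and the camera adjusted p was 0.00758, with an adjusted p of 0.691 with an estimated correlation. Without kat6a replicate 1 the number was 4, namely hsp70.2, hsp70.3, hsp70l and dnajb1b, and without WT replicate 4 it was 1, hsp70.1. With array weights it was 3, namely hsp70.2, hsp70.3 and hsp70l; without the pair numbered 1 these and jun fell while klf2b rose, and with the block and median-ratio scaling these 4 and dnajb1b fell. The heat shock protein genes hsp70l and hsp70.3 were 374 ± 140 and 358 ± 126 FPKM in WT and 190 ± 94.1 and 190 ± 87.8 in kat6a (SD, n = 4), lower in 4 of 4 pairs; near-identical hsp70 copies may share reads. Median-ratio and upper-quartile scaling ended the list's call, at 0.109 and 0.425, and upper-quartile scaling put its median at 0.031, whereas quantile normalisation gave 6.45e-06, with an adjusted p of 0.540 with an estimated correlation. Leaving out WT replicate 1, kat6a replicate 2 or kat6a replicate 3 also ended it, up to 0.655, as did a pseudocount of 0.1, no filter, array weights and leaving out the pair numbered 1, at 0.336.

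**Figure D3:**
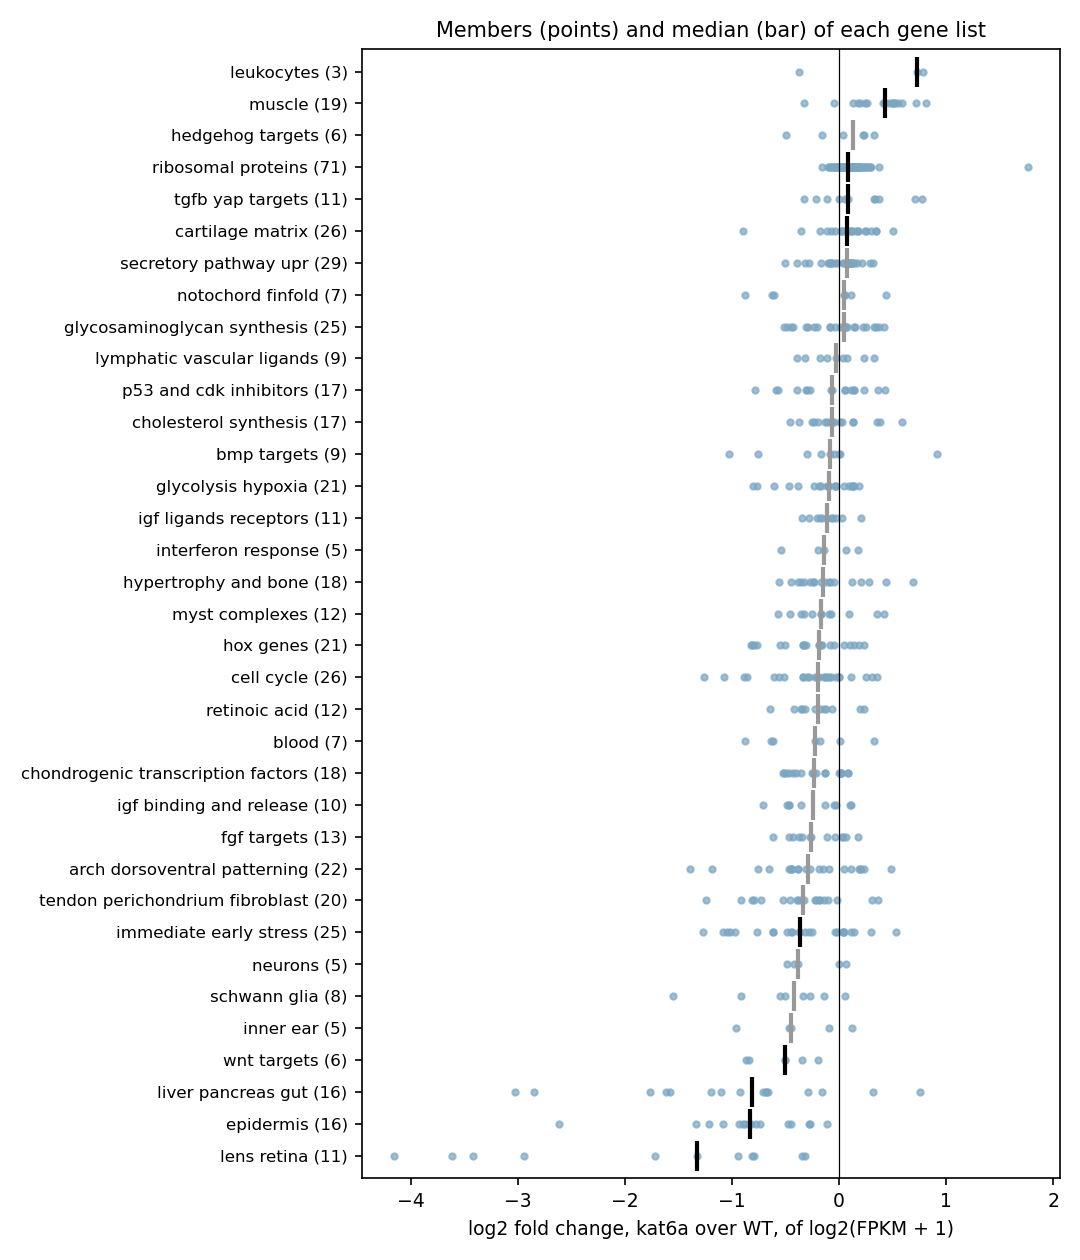
Log2 fold change, kat6a over WT, of each tested member (points) and the median (bar) of the 35 lists, with the number of members in brackets. Black bars mark the 10 lists called by camera at its preset correlation and grey bars the others; the lens and retina list lies lowest, with a median of -1.33.

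No IGF gene passed the limma test over all genes, and pappab alone fell adjusted over the list alone, in 1 fit, with the block and array weights. Of 11 tested IGF ligand and receptor genes and 10 tested IGF binding and release genes limma called none, and 1 of the 21, pappab, had an unadjusted p under 0.05. The ligand gene igf2b was 40.1 ± 6.29 FPKM in WT and 39.2 ± 5.25 in kat6a (SD, n = 4), a log2 fold change of -0.027 with a 95% interval of -0.45 to 0.40. The other igf2 gene, igf2a, was 78.5 FPKM in WT replicate 1 and 44.4 in kat6a replicate 1, against 1.45 to 3.52 in the other 6 libraries. The ligand gene igf1 was listed at 0 in 6 libraries, at 1.69 FPKM in WT replicate 1 and at 0.987 in kat6a replicate 3. Receptor genes igf1ra and igf1rb had log2 fold changes of -0.35 ± 0.35 (SE) and -0.11 ± 0.36, and the adaptor gene irs2a -0.28 ± 0.20. Both igf1ra and irs2a were lower in 4 of 4 pairs, while 69.5% of all tested genes were lower in kat6a by any amount. With the replicate block their unadjusted limma p was 0.102 and 0.0823. Under upper-quartile scaling the signs of igf2a, igf2b, igf1rb, igfbp3 and irs2a turned.

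Among IGF binding proteins, which hold the ligands outside cells, igfbp3 was the most abundant, at 141 ± 32.8 FPKM in WT and 139 ± 35.7 in kat6a (SD, n = 4), with a 95% interval of -0.54 to 0.48 for its log2 fold change. The log2 fold change was -0.47 ± 0.35 (SE) for igfbp1a, -0.36 ± 0.44 for igfbp2b and 0.097 ± 0.21 for igfbp5b. FPKM of igfbp7 was 2.97, 11.3, 10.2 and 7.58 in WT and 0, 8.39, 7.59 and 7.06 in kat6a. Both igfbp1a and igfbp7 were lower in 4 of 4 pairs; with the replicate block igfbp1a had an unadjusted limma p of 0.0287 and an adjusted p of 0.451. The genes igfbp1b, igfbp2a and igfbp5a were listed at or below 1.22 FPKM in every library, and igfbp6a and igfbp6b at 0. The gene pappab, which encodes a protease that cleaves IGF binding proteins, was 37.9 ± 3.67 FPKM in WT and 27.2 ± 5.56 in kat6a, lower in 4 of 4 pairs, with a limma adjusted p of 0.958, or 0.451 with the block. Camera adjusted p was 0.853 for the ligand and receptor list and 0.838 for the binding and release list. The lymphangiogenic ligand gene vegfc was listed at 0 in every library. Of the genes that act on such ligands adamts14 had a log2 fold change of -0.32 ± 0.25 and svep1 of -0.40 ± 0.29, and the lymphatic and vascular ligand list had an adjusted p of 0.754.

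**Figure D4:**
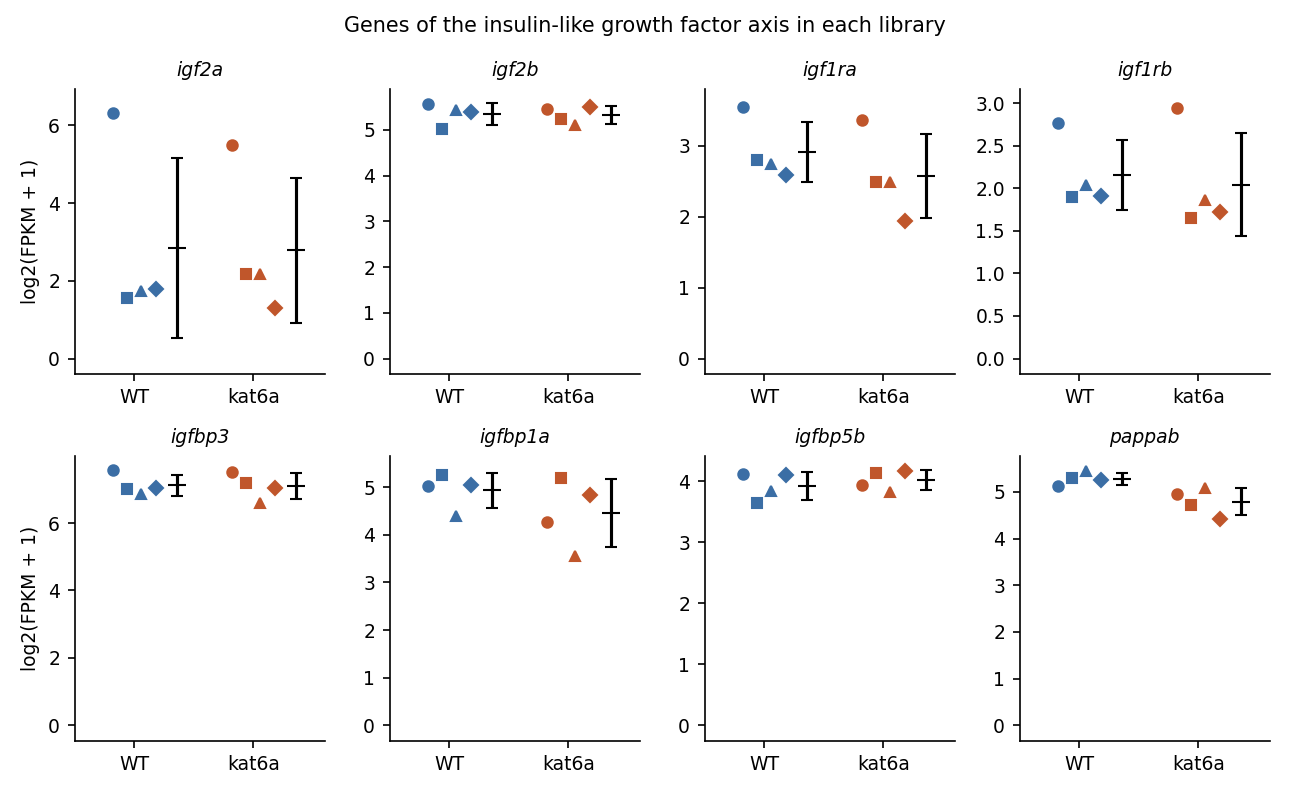
FPKM of 8 genes of the IGF axis on a log2(FPKM + 1) scale, with 1 point per library, circle, square, triangle and diamond for replicates 1 to 4, and bars for the mean and SD of log2(FPKM + 1) (n = 4). The libraries numbered 1 hold the highest igf2a values, 78.5 and 44.4 FPKM, while igf2b lies between 31.3 and 46.3 FPKM in all 8.

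Some patterning genes had lower values in kat6a, and none passed the test over all genes or, with or without the replicate block, over the list alone. Among hox genes, which set segment identity, hoxb2a was 1.35 ± 0.536 FPKM in WT and 0.312 ± 0.171 in kat6a and hoxa1a 1.39 ± 0.661 and 0.334 ± 0.195 (SD, n = 4), each lower in 4 of 4 pairs with a limma adjusted p of 0.958. The hox list had a camera adjusted p of 0.667 over 21 members, 2 of which had an unadjusted p under 0.05. In the pharyngeal arch patterning list, with an adjusted p of 0.729 over 22 members, msx1b was 2.36, 4.46, 2.74 and 5.70 FPKM in WT and 2.83, 0.615, 1.75 and 0 in kat6a.

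The other signalling and cell state lists were not called without the block. In the BMP list, adjusted p 0.838, the inhibitory gene smad6b was 10.5 ± 1.23 FPKM in WT and 5.80 ± 1.15 in kat6a (SD, n = 4); with the replicate block smad6b and id1 fell adjusted over the list alone, without a filter smad6b and msx2b, and with array weights smad6b. The cell cycle list, which was higher in the libraries numbered 1 of both groups, had an adjusted p of 0.943, and it was called lower when that pair was left out, at 0.00946, and without kat6a replicate 1, at 0.000345. With an estimated correlation the adjusted p there was 0.724 and 0.680. Its members mcm6 and mcm7, of the replication helicase, had log2 fold changes of -1.07 ± 0.48 (SE) and -1.26 ± 0.60, and the CDK inhibitor gene cdkn1a, of the p53 list at 0.510, had -0.78 ± 0.32. The tendon and perichondrium list had an adjusted p of 0.259 and was called lower with the block, at 0.0450, with an adjusted p of 0.668 with an estimated correlation; twist2 was 5.04, 2.59, 3.41 and 4.21 FPKM in WT and 0, 2.503, 2.22 and 0.392 in kat6a. The secretory pathway list was called higher without WT replicate 2, 3 or 4 or kat6a replicate 3, down to 0.00248, and under median-ratio scaling, with or without the block, or upper-quartile scaling, down to 0.00194; with an estimated correlation the adjusted p in these fits was 0.607 to 0.802. With the block and array weights mcm4, mcm6 and mcm7 of the cell cycle list, srebf2 of cholesterol synthesis and col6a1, col6a2, col5a1 and col5a2a of the tendon list fell adjusted over the list alone. Camera adjusted p was 0.606 for chondrogenic transcription factors, 0.726 for hypertrophy and bone, 0.495 for hedgehog, 0.978 for FGF and 0.853 for retinoic acid. It was 0.0869 for the secretory pathway, where the chaperone gene hspa5 was 277 ± 23.9 FPKM in WT and 223 ± 35.5 in kat6a, 0.838 for glycolysis and hypoxia, 0.310 for cholesterol synthesis and 0.853 for interferon response. Among markers of other cells it was 0.357 for Schwann cells and glia, or 0.0454 without the pair numbered 1 (adjusted p of 0.649 with an estimated correlation), 0.754 for neurons, 0.838 for blood, 0.470 for the inner ear and 0.754 for notochord and fin fold. Pigment cell and mitochondrial genome lists had 0 tested members and the endothelial list 1, fli1a, at -0.28 ± 0.27. Camera compares a list with the other genes, so 9 of the 35 lists had an upward camera direction with a median below 0; the median and mean differed in sign for glycosaminoglycan synthesis and for notochord and fin fold.

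A mutated locus can carry linked variation, so changed genes were counted by chromosome. Neither mipb nor cryba4 lies on the chromosome of kat6a, where 610 tested genes were placed beside 9815 elsewhere. At an unadjusted p under 0.05 29 of those 610 genes and 421 of the 9815 were counted, an odds ratio of 1.11 with a 95% interval of 0.730 to 1.64 and a Fisher's exact p of 0.539. With the replicate block it was 1.02, from 0.768 to 1.34. Of the 100 tested genes nearest to kat6a 8 had an unadjusted p under 0.05, or 13 with the block. On the other chromosomes it was 421 of 9815 genes, or 1012 of 9815 with the block. The neighbours were not tested apart from the chromosome.

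The authors' deposited table, whose fold is WT over kat6a, held 0 genes with q under 0.05. It held 758 genes with p under 0.05, 509 higher in WT and 249 higher in kat6a, and its smallest q was 0.169. For mipb the authors' deposited table gave a fold of 7.70 with q = 0.169, and for cryba4 13.02 with q = 0.271. For kat6a that deposited fold was 1.09 with q = 0.902. Over the 11763 tested genes the sign of the authors' deposited fold matched that of the limma fold change for 78.2%, and the Spearman correlation across genes, which are not independent replicates, was 0.816. Both tests gave a p under 0.05 for 253 genes, against 581 in the authors' deposited table and 537 in limma among those tested.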

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

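Each group of 4 libraries was searched for a library whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value, over 256 groups of named genes, lists and library measures; the tests of explanations were chosen after the results were seen. A total of 37 groups held such a library, where chance gives about 1 in 20, or 12.8, and 25 of the 37 were a library numbered 1. In 5 of them 1 library had a value and the other 3 were listed at 0, which meets the rule by construction: igf1 in both groups and igfbp5a, igfbp2a and fmodb in kat6a. Without such groups 32 of 251 held one, where chance gives about 12.6, and 23 of the 32 were a library numbered 1.

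Among genes, WT replicate 1 stood above the other WT libraries for mcm7 (16.7 FPKM), lef1 (4.13), igf2a (78.5), igf1rb (5.83) and igf1 (1.69). The kat6a library numbered 1 stood above the others for foxf1 (13.5), igf1rb (6.67) and igfbp5a (0.233) and below them for igfbp2b (0.164) and igfbp7, listed at 0. For mean log2(FPKM + 1) of a list, WT replicate 1 was high for IGF ligands and receptors (4.19), hox genes (2.68), arch patterning (2.38), cell cycle (3.36), WNT targets (2.83), FGF targets (4.54), cholesterol synthesis (3.00) and immediate early and stress genes (7.54), and low for cartilage matrix (8.38) and the secretory pathway (5.38). The kat6a library numbered 1 was high for lymphatic and vascular ligands (3.19), hox genes (2.29) and Schwann cells and glia (1.76). It was low for cartilage matrix (8.61) and the share of the 10 genes with the highest mean over the 8 libraries (16.1%).

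The other libraries that stood apart were kat6a replicate 3 for fmodb (0.313 FPKM), igfbp1b (1.22), igf1 (0.987) and the muscle list (5.54), kat6a replicate 4 for id4 (listed at 0), rdh10b (1.89) and WNT targets (1.45), kat6a replicate 2 for rpl29 (223) and igfbp2a (0.125), WT replicate 2 for smad6b (8.64), and WT replicate 4 for rpl35 (863) and the notochord and fin fold list (3.74).

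The libraries numbered 1 stood above the other 3 of their group in both groups for 4048 of 11763 tested genes and below them for 1030. Sequencing depth stays open, since FPKM keeps no counts. A lower share of chondrocytes cannot be told apart from other explanations. Cartilage matrix genes were below the other 3 libraries in both groups for 65.4% of members and above them for 19.2%, against 8.76% and 34.4% of all tested genes, which goes with such a share. It would raise the markers of every other cell type, while of 11 such lists 2, tendon with perichondrium and Schwann cells with glia, lay above the other 3 libraries in both groups and 2, leukocytes and lens, lay below; those below rest on few or low genes. The libraries with this number deviated together, with r = 0.589 across genes, which is consistent with a condition shared by them, such as a day or a stage; the labels name none. No biological explanation was tested, because the design gives no group that follows the number.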

How the results depend on the processing

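Combinations of the block with another setting, the omission of the pair numbered 1 and the chromosome counts at an unadjusted p were chosen after seeing the data, the last because too few genes passed the adjusted threshold. The count of 2 called genes, all at least 2-fold, was 2 with a mean FPKM of at least 1 and with robust limma, and the same genes were called there. It was 1 with a pseudocount of 0.1, 0 with no filter, 0 with median-ratio, quantile or upper-quartile scaling, 1 with the replicate block, 14 with array weights, 4 without the pair numbered 1, 0 with the block and median-ratio scaling, and 5 with the block and array weights; every such gene was also at least 2-fold changed, and the cause was not tested. Leaving out 1 library gave between 0 and 5 genes. The count of 10 lists was 6 with quantile normalisation, 5 with array weights, 0 with an estimated correlation, 1 with fry and from 5 to 12 with 1 library left out; the cause was not tested. Muscle, liver with pancreas and gut, and lens with retina were called by camera in the same direction in all 20 alternative fits. Camera did not use the robust setting, so the robust limma fit among them could only repeat the main result. Over the lists 42 calls were lost and 22 gained among 699 values. That count leaves out the cartilage matrix call without WT replicate 1, which was also lost and whose direction turned. The cartilage matrix mean ranged from -0.093 in that fit to 0.16 with 1 library left out. Members called with p adjusted over the list alone numbered 0 to 11 for muscle and for liver with pancreas and gut, 0 to 2 for leukocytes, 4 to 8 for lens with retina, 0 to 10 lower ones for immediate early and stress genes and 0 to 9 for ribosomal protein genes. For kat6a the log2 fold change passed an unadjusted p of 0.05 with the replicate block (-0.46), without kat6a replicate 1 (-0.78), without the pair numbered 1 (-0.56) and with the block and array weights (-0.38), and it ranged from -0.78 to -0.24 with 1 library left out; its limma adjusted p was 0.322 or more in every fit, and the unadjusted threshold for this gene was set after its p-values were seen. Upper-quartile scaling put it at -0.086. Genes at an unadjusted p under 0.05 numbered 537, or 1224 with the block, and beyond the results given in the report the block changed no other call. Genes called on the chromosome of kat6a numbered 0, also at least 2-fold and by the authors' deposited q, and 29 at an unadjusted p under 0.05 or 64 with the replicate block. Named genes had the opposite sign in 61 of 1704 alternative values, over 18 genes, none called in either fit; under upper-quartile scaling these included adamts14, hspa5, xylt1 and fli1a. With 1 library left out 48 of 86 named genes moved by over 1.5 times or turned. Count tests and unsummed rows were not run, since the table holds no counts and 1 row per gene. Depth is unknown, and the median half-width of the 95% interval of a log2 fold change was 0.75, or 0.58 for the 3035 genes with a mean FPKM of at least 10.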

Other observations

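The tests in this part were chosen after the values were seen, except that of the chromosome of kat6a, whose bounds were set before its own result was seen but after the number of called genes was known. The gene tnxba, of the extracellular matrix protein tenascin, stood at 461 ± 106 FPKM in WT and 1082 ± 299 in kat6a (SD, n = 4), with no overlap and higher in 4 of 4 pairs. Its log2 fold change was 1.22 ± 0.23 (SE) with a limma adjusted p of 0.268, and array weights alone called it, at 0.0332, among adjusted p from 0.0332 to 0.919 over the alternatives. The gene ubb, for ubiquitin, was 75.9, 40.8, 44.4 and 63.3 FPKM in WT and 51.7, 5.08, 5.85 and 9.34 in kat6a. It was called lower with array weights, without kat6a replicate 1 and without the pair numbered 1. Genes higher in both libraries numbered 1 included hand2, a ventral arch gene, at 89.2 and 74.0 FPKM against 1.24 to 5.66 in the other 6, and the collagen gene col8a2, at 4037 and 2679 against 134 to 268.

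Splits of the 8 libraries into 4 and 4, 35 in all, were used to ask whether chance can be excluded. As many as 2 called genes came from 3 of the 35 splits, the real one included, and the highest other split gave 3, so chance cannot be excluded for the count of called genes or for that of genes changed at least 2-fold, where the numbers were the same. The 3 splits were all among the 8 that part all 4 pairs. As many lists as the 10 called by camera came from 10 of the 35 splits, with 13 in the highest other, so chance cannot be excluded for that count, and among the 8 splits that part all pairs the real one alone reached it. For fry the real split called 1 list and the others 0, which is 1 of 35. The lens and retina list was singled out after it was seen to lie lowest of the 35 lists, so each split was measured by its own largest list mean, whichever list that was. The real split gave 1.86 in size, from the lens list, and the highest other split 1.47, again 1 of 35, which over all 35 splits argues against chance for the lens genes. Among the 8 splits that part all 4 pairs, with 1.22 in the highest other, there are too few for a share under 0.05, for fry as for the lens list; the remaining splits leave the 2 libraries of some pairs in the same group.

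For the lower lens genes, reads shared between crystallin copies are argued against by the sum over 56 crystallin genes, whose log2 ratio of means was -3.97, or -5.996 without kat6a replicate 4, with no overlap between groups. A fall of every other tissue alike in the kat6a libraries does not go with the muscle list, with a median of 0.42. That list had a camera adjusted p of 0.464 with an estimated correlation. Medians of leukocyte and of notochord and fin fold markers were also above 0. Those of lens, epidermis, liver, inner ear, Schwann cell, neuron, tendon and blood markers ran from -1.33 to -0.23. The median of all tested genes was -0.16, so less RNA of most other tissues stays open. Whether lens RNA reached the sorted cells to a different extent in the tubes of the 2 genotypes cannot be told apart from genotype, since each library holds cells of 1 genotype; 8 crystallin genes had a median range of 1.72 over the WT libraries on the log2 scale, beside a median log2 fold change of -3.36 between the groups. The sort on both reporters would be expected to remove lens cells, and crystallins held 0.0606% of WT FPKM. A lower lens content or lens expression in kat6a-deficient larvae may be the source and stays open as a hypothesis.

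For the lower heat shock genes, scaling as the whole cause is argued against by their median log2 fold change of -0.89 after median-ratio scaling, from -1.04 before, over 5 genes that stayed below 0 under each scaling. It was -1.08 after quantile normalisation and -0.65 after upper-quartile scaling, which took away part of the difference; the middle gene, hsp70l, had an SE of 0.36 before and 0.29 after median-ratio or upper-quartile scaling. Handling of the sorted cells may have differed between the tubes of the 2 genotypes. Deviations of heat shock and of 6 immediate early genes from their group means had a Pearson r of 0.573 over 8 libraries (exact permutation p 0.158) and a Spearman rho of 0.19 (exact permutation p 0.665). Without the 2 libraries farthest from the median r was 0.68, and since each library holds 1 genotype, handling and genotype cannot be told apart.

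A hypothesis that changed genes gather on the chromosome of kat6a, as linked variation would give, had an odds ratio of 1.11, with an interval of 0.730 to 1.64. With the replicate block it was 1.02, from 0.768 to 1.34. The bound of 1.5 set beforehand for the upper end was met with the block, which argues against an excess of that size there, and not without it, so the 2 fits leave it open. By adjusted p, 1 of the 25 chromosomes, another one, passed, at 0.0361 with an odds ratio of 1.87. A hypothesis that hox genes of paralog groups 1 to 4 fell more than those of higher groups was tested on 9 and 12 genes. Mean log2(FPKM + 1) of the first set was 1.59 ± 0.404 in WT and 1.16 ± 0.271 in kat6a (SD, n = 4), with an exact permutation p of 0.114 and lower in 4 of 4 pairs. The difference between the sets gave an exact permutation p of 0.629, so the data do not decide.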
